A study of Homo sapiens with 12 samples.

How the data were processed

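RNA of 12 H6c7 libraries was sequenced, 3 each from untransduced (parental) cells, cells given a GFP lentiviral vector at 575 infection units per cell, and cells given an HBP1 lentiviral vector at 3.25 (low dose) or 32.5 (high dose) infection units per cell. Per the labels' protocols, cells grew in serum-free keratinocyte medium with EGF and pituitary extract, stayed with the virus for 24 h, and were frozen 72 h after transduction. Per the same protocols, RNA was taken up on RNeasy columns and libraries were made with a kit that does not keep strand. Per the submitters' processing notes, CASAVA, STAR and DESeq2 were used with build hg38, and no versions are given there. The read counter and the annotation are not given in the sources used here.

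The deposited table holds a normalized signal: gene read counts that the authors divided by 1 size factor per library, as the values themselves show. In every library, 100% of values were whole multiples of a single step within a tolerance of 0.001 reads, so whole reads could be recovered. The libraries held 14678322 to 18767054 recovered reads, with size factors of 0.918 to 1.136 and 25176 to 28172 genes with a read. The table has 57167 named genes without duplicates, of which 57142 (99.96%) are in GENCODE 29 and 25 are symbols turned into calendar dates by spreadsheet software. Those 25 stayed in the fits and were treated as having no symbol. Coordinates come from GENCODE 29.

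A linear model was fitted with limma 3.58.1 in R 4.3.3 to log2(deposited value + 1), with 1 mean per group over all 12 libraries and the trend option of the empirical Bayes step. Genes needed a deposited value of at least 10 in at least 3 libraries, which left 18029. The 6 pairwise comparisons of the 4 groups and an F test over the groups were made two-sided, and p-values were adjusted by Benjamini-Hochberg within each comparison with a threshold of 0.05. Fold changes on this scale understate the change of low genes. Replicate number was not a term, because no label says that it marks a shared day or batch. Low genes were compared by their summed whole reads, with a 95% interval for the ratio of counts, and such intervals cover counting error only.

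Gene lists were tested with camera in limma, with a preset correlation of 0.01 between genes, and adjusted over 26 lists within each comparison. The lists cover G1/S, G2/M, histone, p53 target, CDK inhibitor, reported HBP1 target, Wnt/beta-catenin, interferon-stimulated, NF-kB, AP-1, unfolded protein response, ATF4, cholesterol synthesis, hypoxia, NRF2, TGF-beta, duct, squamous, adhesion, ribosomal protein and mitochondrially encoded genes, and acinar, islet, fibroblast, endothelial and leukocyte markers. All 565 members were matched to the table, 24 of them through an older symbol. Members rising or falling were counted over all genes tested and again adjusted over the list alone. In the high-dose against GFP vector comparison, 10 lists passed and 6 of them still passed with an estimated correlation. The corresponding numbers were 13 and 2 for low dose against GFP vector, 15 and 4 between the doses, 11 and 2 for GFP vector against parental, 9 and 4 for high dose against parental, and 13 and 3 for low dose against parental.

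The groups, the tests, the gene lists, the rule for naming genes and the alternatives were fixed before the data were examined, except where stated. That rule named HBP1 in every comparison. It named the 12 largest rises and the 12 largest falls in the comparisons of each dose with GFP vector, of the doses with each other and of GFP vector with parental cells, and the 5 largest each way in the comparisons of the HBP1 groups with parental cells. Such genes had to pass the threshold, have no overlap of values between the groups, average at least 100 in the higher group and carry an ordinary symbol. Up to 4 members per list and comparison with the smallest adjusted p, and all CDK inhibitor and reported HBP1 target genes, were named as well. Names ending in P and digits were left out only where GENCODE types them as pseudogenes, and clone names and date names counted as no symbol. The text gives a selection of these genes, and some results are not reported here. Both doses were compared with the same GFP vector libraries, so their overlap was set beside 100 simulated draws without change.

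The alternatives were pseudocounts of 0.5 and 10, no filter on low values, a minimum of 50, TMM and upper-quartile scaling, a block for replicate number, a fit to only the groups compared, array weights, edgeR 4.0.16 quasi-likelihood and DESeq2 1.42.0 tests on the recovered reads, a threshold of 0.01, an estimated correlation and the fry test for lists, and leaving out each library in turn. A fit without high-dose replicate 3 and GFP vector replicate 2 was added after the data had been seen. Tables were handled in python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.

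The fit was tested on simulated data for 17306 genes, drawn from parental mean levels and library depths with the same spread setting for every gene. Changed genes were placed in the high-dose against GFP vector comparison. The spread was not matched to the real libraries of that comparison, so the rates that follow may not hold for them. Of 50 genes changed at each size, 22% were recovered at 1.5-fold, 70% at 2-fold and 100% at 4-fold and 8-fold, with 10 false calls (6.4%). A simulated GFP vector against parental comparison without changed genes gave 0 false calls in limma. A list shifted by 0.5 in a simulated low-dose against GFP vector comparison was found with camera adjusted p = 1.6e-21, and 0 of 25 other lists were called. Because the simulated genes were not correlated, this cannot show how often correlation between genes leads to a false list call. Differences between the doses were tested gene by gene and over gene lists, and those flagged for a closer look were chosen over gene lists only. Vector sequences were not searched, because reads were not analysed here, and raw-read quality was not analysed here.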

Results

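H6c7 is an immortalised line derived from normal human pancreatic duct epithelium. RNA was sequenced from 12 libraries in 4 groups of 3. Parental cells received no virus. GFP vector cells received a lentiviral vector carrying green fluorescent protein at 575 infection units per cell. Low-dose and high-dose HBP1 cells received a lentiviral HBP1 vector at 3.25 and 32.5 infection units per cell, and transduced cells were harvested 72 h after the virus was added. The libraries held 14678322 to 18767054 reads assigned to genes. Levels are normalised read counts, given as mean ± SD (n = 3 libraries per group). Log2 fold changes are on the log2(value + 1) scale and carry the SE of a limma fit over all 12 libraries, in which 18029 genes were tested. Every adjusted p measures the spread between libraries alone, because the labels do not say whether the 3 libraries of a group came from separate cultures. The kit did not mark strand, so reads from a gene and an antisense partner cannot be told apart.

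HBP1, the gene carried by the vector, was measured in every group before any other gene. It encodes an HMG-box transcription factor studied mainly as a repressor of cell cycle and Wnt target genes (ENSG00000105856.13; build hg38, chromosome 7, 107168961 to 107202529, plus strand). HBP1 stood at 254 ± 15.6 normalised counts in parental cells, 277 ± 26.4 in GFP vector cells, 578 ± 40.5 in low-dose cells and 1040 ± 86.6 in high-dose cells. The high dose raised HBP1 by 1.90 ± 0.10 (log2, SE) against GFP vector cells, a 3.74-fold difference (95% confidence interval 1.70 to 2.11 on the log2 scale; adjusted p = 1.4e-13). The low dose raised it by 1.06 ± 0.10, or 2.08-fold (adjusted p = 2.8e-08), and the high dose exceeded the low dose by 0.85 ± 0.10 (adjusted p = 1.5e-07). HBP1 did not differ detectably between GFP vector and parental cells (0.12 ± 0.10, adjusted p = 0.47). Above the GFP vector mean, HBP1 gained 300.4 counts at the low dose and 763 at the high dose, a ratio of 2.54 for 10 times as much virus. Reads from the vector's HBP1 and from the cells' own gene are summed in these values.

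**Figure D1:**
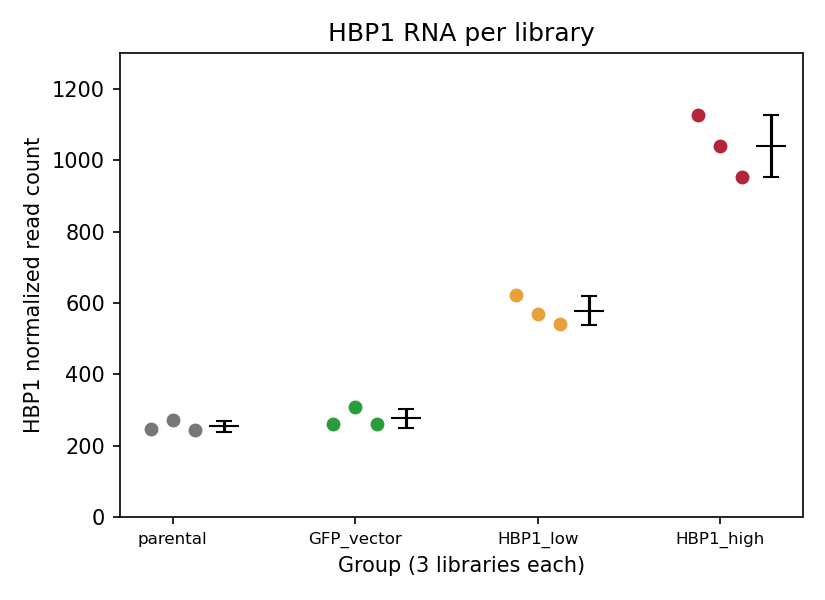
HBP1 in each of the 12 libraries, in normalised read counts (vertical axis, from 0), by group, with the mean and SD of each group. The 3 high-dose libraries lie between 953.1 and 1126.4, the 3 low-dose libraries between 541.9 and 621.7, and the 6 control libraries between 244.3 and 307.8.

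Across all genes, the libraries separated by group. The leading principal component held 40.5% of the variance and set the high-dose libraries, at 70.09 to 74.24, apart from the other 9, all at or below -0.26. The next component held 20% and set the low-dose libraries apart, at -53 to -32.88. GFP vector replicate 2 stood away from its group on the component after that, at -40.03. Mitochondrial transcripts took 8.06% ± 0.3 of reads in parental cells, 5.66% ± 0.57 in GFP vector cells, 6.42% ± 1.08 in low-dose cells and 12.5% ± 4.58 in high-dose cells. High-dose replicate 3 had the highest mitochondrial share, 17.61%, beside 8.81% and 11.04% in the other high-dose libraries. Over the 4 groups, an F test in limma called 12133 genes (67.3%).

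**Figure D2:**
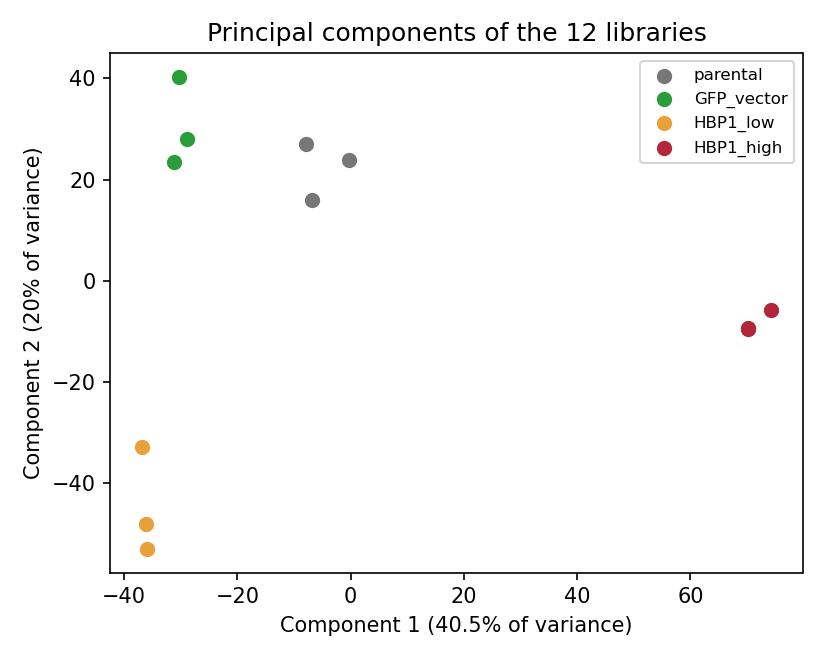
Scores of the 12 libraries on the leading principal components of log2 normalised counts, with the share of variance on each axis and colours for the 4 groups. The high-dose libraries lie at 70.09 to 74.24 on the leading axis, and the low-dose libraries at -53 to -32.88 on the next.

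**Figure D3:**
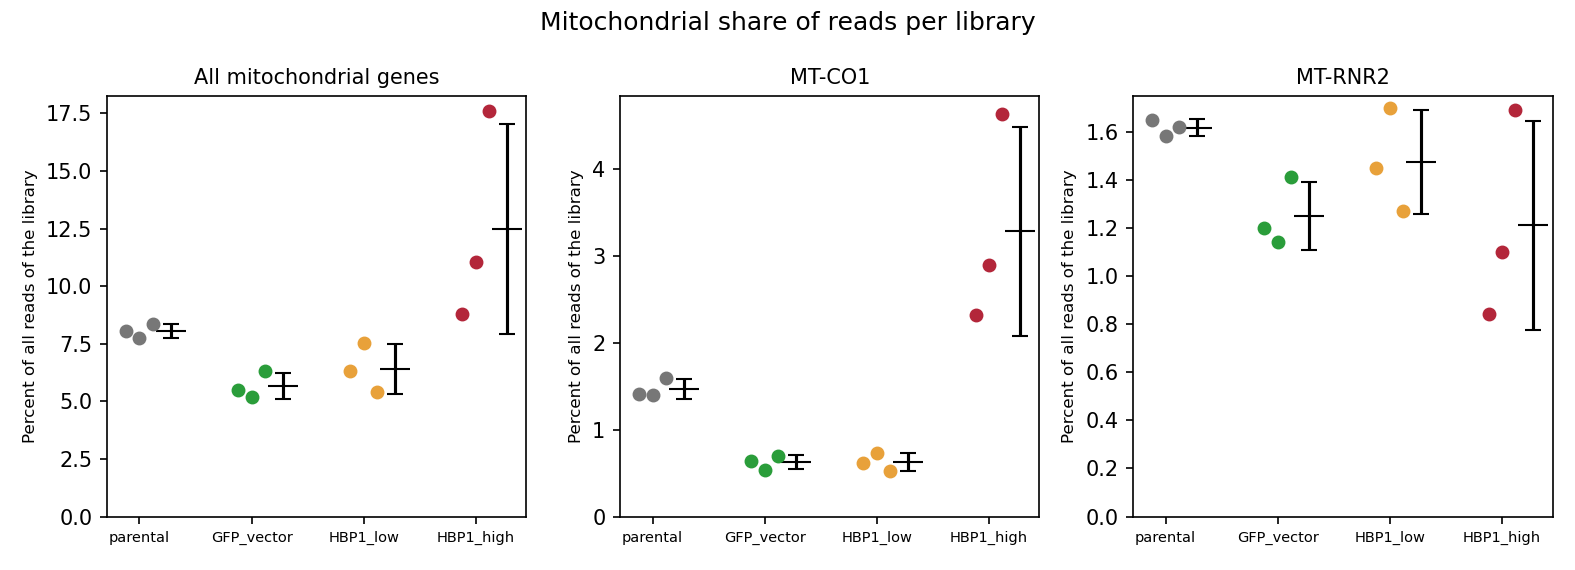
Percent of reads in each library from all mitochondrially encoded genes, from MT-CO1 and from MT-RNR2, by group, with group mean and SD. For all mitochondrial genes, high-dose libraries lie at 8.81%, 11.04% and 17.61%, GFP vector libraries between 5.2% and 6.3%.

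The comparison of high-dose HBP1 with the GFP vector asks what strong HBP1 expression does in a normal duct line against a transduced control. The list that moved furthest was that of interferon-stimulated genes. MX2, an interferon-induced GTPase that blocks incoming viruses, stood at 64.1 ± 9.11 in high-dose cells against 12200 ± 641 in GFP vector cells (log2 fold change -7.56 ± 0.10, adjusted p = 1.6e-24). RSAD2, which encodes the antiviral enzyme viperin, stood at 362 ± 14.2 against 25200 ± 2290 (-6.11 ± 0.13, adjusted p = 1.1e-20). IFI44L fell by 5.69 ± 0.10 on the log2 scale and CMPK2, a mitochondrial nucleotide kinase induced by interferon, fell by 5.64 ± 0.12. All 32 interferon-stimulated genes tested fell, over all genes and adjusted over the list alone, with a median of -4.07 (camera adjusted p = 1.3e-50). CXCL10, an interferon-induced chemokine outside that list, stood at 15.3 ± 6.49 against 4280 ± 355 (-8.10 ± 0.19, adjusted p = 2.2e-20). Genes near zero in high-dose cells are given as read ratios with 95% intervals that cover counting error only. ZBP1, a sensor of left-handed nucleic acids, had 2 reads in the 3 high-dose libraries and 1005 in the 3 GFP vector libraries, a ratio of 580 (160 to 4800) after scaling. The guanylate-binding protein gene GBP5 had 8 against 740 (ratio 107, 53.9 to 248).

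Inflammatory genes fell with them at the high dose. CXCL2, a neutrophil-attracting chemokine, stood at 592 ± 62.9 against 4060 ± 240 in GFP vector cells (log2 fold change -2.78 ± 0.09, adjusted p = 1.3e-17), and CXCL8 at 99 ± 8.91 against 684 ± 18.4 (-2.78 ± 0.13, adjusted p = 2.9e-14). BIRC3, an inhibitor of apoptosis induced by NF-kB, fell by 2.93 ± 0.11 on the log2 scale. Of 22 NF-kB and inflammatory cytokine genes, 21 fell and 1 rose, adjusted over all genes and adjusted over the list alone (median -1.28, camera adjusted p = 2.4e-14). TNFSF18, a ligand of the tumour necrosis factor family, fell from 768 ± 38.6 to 8.53 ± 0.648, and the collagenase gene MMP13 from 496 ± 72.6 to 8.48 ± 2.95. Genes of the amino acid response also fell, 19 of 20 in the ATF4 list and 19 adjusted over the list alone (median -0.89, camera adjusted p = 1.5e-11). Among them, asparagine synthetase (ASNS) stood at 238 ± 54.5 against 1040 ± 144 (-2.14 ± 0.12, adjusted p = 1.1e-12), and STC2 and CHAC1 fell by 2.46 ± 0.11 and 2.67 ± 0.14. PPP1R15A, whose product reverses the translational block of the integrated stress response, fell by 2.52 ± 0.11, from 10200 ± 1120 to 1770 ± 56.2. Its own list, the unfolded protein response, was mixed, with 6 of 18 genes up and 7 down, and the same numbers adjusted over the list alone (median -0.08, camera adjusted p = 0.44).

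Cell cycle genes rose at the high dose. E2F1, the transcription factor that drives entry into S phase, stood at 1170 ± 41.4 against 320 ± 13.3 in GFP vector cells (log2 fold change 1.87 ± 0.10, adjusted p = 3.2e-13). PCNA, the sliding clamp of the replication fork, stood at 1890 ± 76 against 795 ± 9.19 (1.25 ± 0.08, adjusted p = 2.9e-12), and FEN1 and UHRF1 rose by 1.5 ± 0.10 and 1.32 ± 0.09. Of 31 G1/S and DNA replication genes, 26 rose, also 26 adjusted over the list alone, with a median of 0.88 (camera adjusted p = 1.1e-14). Of 34 G2/M and mitosis genes, 27 rose, and 30 adjusted over the list alone, with a median of 0.45 (camera adjusted p = 2.6e-09). ANLN, KIF20A and AURKB, which act in cell division, rose by 1.03, 1.07 and 0.88. Replication-dependent histone genes showed no shared direction, with 2 of 14 up and 2 down, the same adjusted over the list alone (median 0.29, camera adjusted p = 0.77).

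The genes through which HBP1 has been reported to act did not move as 1 group. MYC, which HBP1 is reported to hold back, stood at 1800 ± 80.6 in high-dose cells and 4060 ± 319 in GFP vector cells (log2 fold change -1.17 ± 0.08, adjusted p = 4.2e-11). H1F0, the linker histone gene that HBP1 is reported to switch on, fell from 11800 ± 1050 to 3020 ± 402 (-1.97 ± 0.11, adjusted p = 5.3e-13). EZH2 and DNMT1, a histone and a DNA methyltransferase gene reported as repressed by HBP1, rose by 0.72 ± 0.09 and 0.55 ± 0.08. Of 9 reported HBP1 target genes, 2 rose and 2 fell, and 3 and 2 adjusted over the list alone. Their median was 0.12 and their mean -0.17, with the list test pointing down (camera adjusted p = 0.98). Among 7 CDK inhibitor genes, which brake the cell cycle, 2 rose and 2 fell, also adjusted over the list alone (median 0.19, camera adjusted p = 0.67). CDKN2B rose by 0.48 ± 0.09 and CDKN1C by 1.28 ± 0.23, while CDKN1B fell by 0.38 ± 0.09 and CDKN2C by 0.53 ± 0.16. The fall of CDKN2C was lost without high-dose replicate 3 (adjusted p = 0.06). CDKN1A, the p21 gene, was not past the threshold (0.19 ± 0.09, adjusted p = 0.078), but passed it without GFP vector replicate 2 (adjusted p = 0.028) or high-dose replicate 2 (adjusted p = 0.017). CDKN2A (-0.04 ± 0.12, adjusted p = 0.79) did not differ detectably. Of 24 p53 target and growth arrest genes, 5 rose and 11 fell, also adjusted over the list alone (median -0.19, camera adjusted p = 0.11), and the list test passed without high-dose replicate 3 (adjusted p = 0.043). GDF15, a secreted stress factor in that list, fell by 2.91 ± 0.10, from 1430 ± 179 to 189 ± 20.9. Wnt/beta-catenin targets went both ways, with 5 of 13 up and 5 down, and 6 and 5 adjusted over the list alone (median 0.15, camera adjusted p = 0.67).

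Metabolic genes rose at the high dose. PFKFB4, which sets the rate of glycolysis, stood at 1240 ± 52.5 against 104 ± 11 in GFP vector cells (log2 fold change 3.57 ± 0.11, adjusted p = 7.6e-18), and ANGPTL4, a secreted lipase inhibitor induced by hypoxia, at 2780 ± 227 against 394 ± 59.3 (2.82 ± 0.11, adjusted p = 2.4e-16). In the hypoxia and glycolysis list, 14 of 22 genes rose and 2 fell, also adjusted over the list alone (median 0.77, camera adjusted p = 8e-07). HMGCS1, an early enzyme of cholesterol synthesis, stood at 2960 ± 207 against 746 ± 37.9 (1.99 ± 0.11, adjusted p = 5e-13), and 19 of 22 genes of that pathway rose, also adjusted over the list alone. That list's median was 0.59 with camera adjusted p = 2.2e-09, and adjusted p = 0.1 with an estimated correlation. Much of the HMGCS1 difference lies in the GFP vector cells, since HMGCS1 stood at 2200 ± 439 in parental cells. Fewer genes of the pathway rose at the high dose against parental cells than against GFP vector cells. NRF2 oxidative stress genes rose in 14 of 19 cases and fell in 3, also adjusted over the list alone (median 0.46, camera adjusted p = 0.00019, adjusted p = 0.29 with an estimated correlation). The cystine transporter gene SLC7A11 in that list fell by 1.78 ± 0.13. Of 13 mitochondrially encoded genes, 11 rose, also adjusted over the list alone (median 1.29, camera adjusted p = 1.3e-05, adjusted p = 0.42 with an estimated correlation). MT-CO1, a subunit of cytochrome oxidase, rose by 2.40 ± 0.30 (adjusted p = 4.9e-07), and its nuclear copy MTCO1P12, with which it shares reads, held too few (mean 769 against 561300 at the high dose) to account for that rise. These genes moved with the library-wide mitochondrial share, and the list median was 0.99 without high-dose replicate 3, where 9 of 13 genes rose.

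Keratin and squamous differentiation genes changed at the high dose. KRT19, the keratin that marks duct epithelium, stood at 20000 ± 369 against 6730 ± 525 in GFP vector cells (log2 fold change 1.57 ± 0.09, adjusted p = 1.7e-12). SPRR1A and SPRR1B, cross-linked envelope proteins of squamous cells, rose by 3.05 ± 0.19 and 2.26 ± 0.10, and KRT15 by 2.15 ± 0.13. LCN2, an iron-sequestering defence protein placed in the same list, fell by 3.24 ± 0.10, from 2920 ± 472 to 307 ± 20.4. Of 34 basal keratin and squamous genes, 17 rose and 4 fell, and 18 and 6 adjusted over the list alone (median 0.53, camera adjusted p = 0.001, adjusted p = 0.39 with an estimated correlation). Duct epithelial genes as a list were mixed, with 3 of 16 up and 5 down, also adjusted over the list alone (median -0.17, camera adjusted p = 0.84). The bicarbonate transporter gene SLC4A4 in that list fell by 2.07 ± 0.27. Adhesion and tight junction genes split, with 11 of 27 up and 7 down, also adjusted over the list alone (median 0.14, camera adjusted p = 0.33). CLDN1 fell by 1.58 ± 0.12 and JUP rose by 1.03 ± 0.09. TGF-beta and mesenchymal genes showed 8 of 23 up and 4 down, also adjusted over the list alone (median 0.09, camera adjusted p = 0.31). AP-1 and immediate early genes showed 12 of 24 up and 5 down, and 12 and 6 adjusted over the list alone (median 0.22, camera adjusted p = 0.28), with FOS up by 1.87 ± 0.15 and ATF3 down (-1.57 ± 0.09).

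The largest rises outside these lists were PPFIA4 (4.0 ± 0.21), IGFN1 (3.84 ± 0.28) and MFAP5 (3.47 ± 0.25), with CYP24A1, the vitamin D 24-hydroxylase gene, at 1510 ± 217 against 180 ± 19.8 in GFP vector cells. LGALS9B and LGALS9C rose by 2.87 and 3.12, but these near-identical copies share reads and are uncertain. Ribosomal protein genes moved little, with 2 of 34 up and 7 down, and 2 and 4 adjusted over the list alone (median -0.14, camera adjusted p = 0.28). That list's test passed without GFP vector replicate 1 (adjusted p = 0.013) or without high-dose replicate 3 (adjusted p = 0.0086). None of the 5 lists of markers of other cell types was past the threshold. Acinar markers, 3 tested, had a median of 0.57 (camera adjusted p = 0.58), and islet endocrine markers, 6 tested, a median of -0.13 (camera adjusted p = 0.77) with CHGB at 52.4 ± 8.14 against 84.6 ± 14.9. Fibroblast markers, 7 tested, had a median of -0.05 and a mean of -0.34 while their list test pointed up (camera adjusted p = 0.98). Endothelial markers, 7 tested, had a median of 1.03 (camera adjusted p = 0.85), while ROBO4 went against the sign of that median, at 14 ± 6.06 against 52.5 ± 4.44. Leukocyte markers, 5 tested, had a median of 0.94 (camera adjusted p = 0.08), with 3 up, also adjusted over the list alone. In that list CORO1A stood at 324 ± 35.9 against 168 ± 10.8 and CSF1R at 149 ± 19.7 against 64 ± 9.41.

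Over all genes, limma called 8631 (47.9%) between high-dose HBP1 and GFP vector cells, 4219 higher and 4412 lower, of which 1418 and 1047 changed at least 2-fold. Upper-quartile scaling gave 4677 higher and 3937 lower and TMM 3858 and 4776, so which direction holds more genes depends on the scaling. On whole reads, edgeR called 8586 and DESeq2 8416. Vector amount differed between these groups as well as the gene it carried, since GFP vector cells received more infection units than either HBP1 group.

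**Figure D4:**
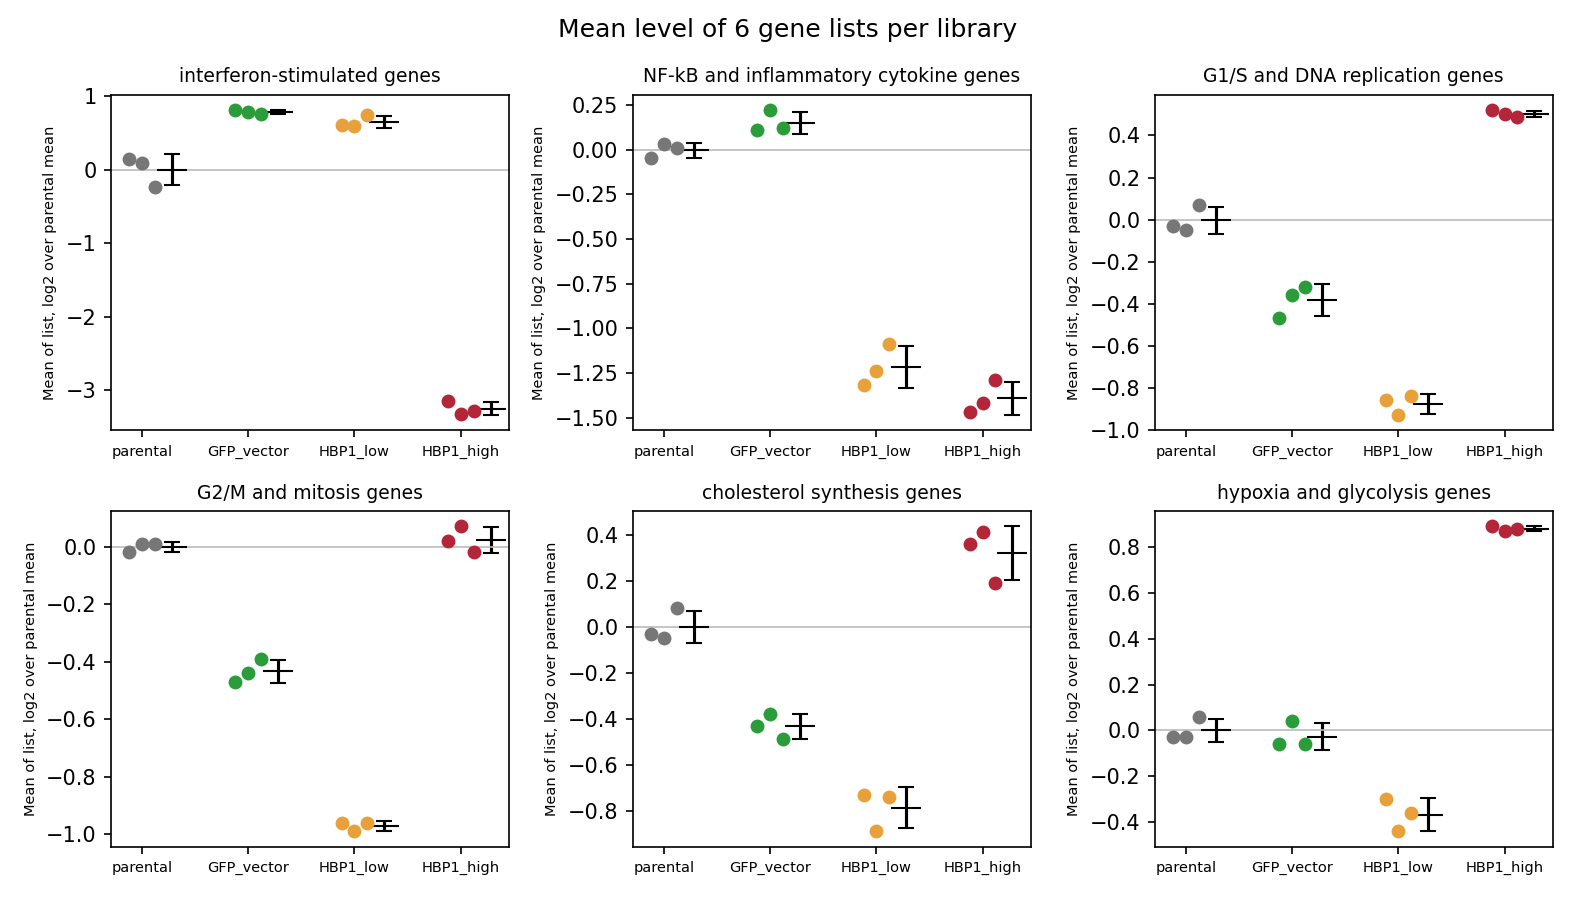
Mean log2 level of 6 gene lists in each library, relative to the parental mean (vertical axis, log2), by group. Interferon-stimulated genes lie between -3.32 and -3.15 in high-dose libraries and between 0.6 and 0.81 in GFP vector and low-dose libraries, while G1/S genes lie at 0.49 to 0.52 in high-dose libraries and -0.93 to -0.84 in low-dose libraries.

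The comparison of low-dose HBP1 with the GFP vector asks the same of a roughly 2-fold HBP1 excess. Here the inflammatory genes fell while most interferon-stimulated genes did not. CXCL8 stood at 109 ± 13.8 against 684 ± 18.4 (log2 fold change -2.64 ± 0.13, adjusted p = 9.3e-13). TNFAIP3, the feedback inhibitor of NF-kB, stood at 812 ± 67.4 against 3010 ± 277 (-1.89 ± 0.09, adjusted p = 3.1e-13), and the cytokine genes CSF3 and CCL20 fell by 1.90 ± 0.09 and 1.98 ± 0.20. All 22 NF-kB and inflammatory genes fell, also adjusted over the list alone, with a median of -1.40 (camera adjusted p = 7e-21). Of 32 interferon-stimulated genes, 4 rose and 5 fell, also adjusted over the list alone (median -0.07, camera adjusted p = 0.23). IFIT3 fell by 1.24 ± 0.10, IFIT2 by 1.17 ± 0.13 and IFIT1 by 0.75 ± 0.12, and MX2 fell by 0.42 ± 0.10, from 12200 ± 641 to 9100 ± 336. CXCL10 fell by 2.10 ± 0.19.

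Cell cycle genes fell at the low dose. RRM2, the ribonucleotide reductase subunit that limits DNA precursor supply, stood at 220 ± 16.3 against 763 ± 72.4 in GFP vector cells (log2 fold change -1.79 ± 0.10, adjusted p = 1e-11). CDK1, the kinase that triggers mitosis, stood at 479 ± 11.3 against 907 ± 40.7 (-0.92 ± 0.08, adjusted p = 1.2e-08), and UHRF1 and DLGAP5 fell by 1.23 ± 0.09 and 1.04 ± 0.09. Of 34 G2/M genes, 30 fell, and 32 adjusted over the list alone (median -0.55, camera adjusted p = 1.7e-15). Of 31 G1/S genes, 20 fell, and 22 adjusted over the list alone (median -0.40, camera adjusted p = 3e-08, adjusted p = 0.15 with an estimated correlation). CDKN1A rose by 0.55 ± 0.09, from 2040 ± 184 to 2980 ± 110 (adjusted p = 4.5e-05). MYC fell further than at the high dose, to 1090 ± 19.1 from 4060 ± 319 (-1.90 ± 0.08, adjusted p = 8.6e-14). H1F0 fell by 0.36 ± 0.11 (adjusted p = 0.013), a call lost without GFP vector replicate 2 (adjusted p = 0.078) or low-dose replicate 1 (adjusted p = 0.063). EZH2 did not differ detectably (-0.13 ± 0.09, adjusted p = 0.29). TP53INP1, a p53-induced stress protein gene, rose by 1.62 ± 0.11, and of 24 p53 targets 7 rose and 3 fell, also adjusted over the list alone (median 0.09, camera adjusted p = 0.13).

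Several further lists passed by camera at the low dose, and all of them fell except the unfolded protein response list, which rose. They were not past the threshold once the correlation between genes was estimated, each at adjusted p = 0.38 with an estimated correlation. Ribosomal protein genes fell in 29 of 34 cases, also adjusted over the list alone (median -0.45, camera adjusted p = 5.3e-11), with RPL7 down from 3300 ± 291 to 1840 ± 97.8. Cholesterol synthesis genes fell in 12 of 22 cases, 13 adjusted over the list alone, and 1 rose (median -0.32, camera adjusted p = 0.00025), with FDFT1 down (-0.90 ± 0.09) and INSIG1 up (0.66 ± 0.09). Unfolded protein response genes rose in 10 of 18 cases and fell in 1, also adjusted over the list alone (median 0.41, camera adjusted p = 0.00086), with the chaperone genes DNAJC3 and MANF up by 0.79 ± 0.10 and 0.69 ± 0.10. Squamous genes fell in 14 of 34 cases and AP-1 genes in 9 of 24, also adjusted over the list alone (medians -0.28 and -0.19, camera adjusted p = 0.0036 for both). KRT14 fell by 1.24 ± 0.14, TP63 by 0.56 ± 0.09 and EGR1 by 2.27 ± 0.14. KRT19 fell to 3360 ± 134 from 6730 ± 525 (-1.0 ± 0.09, adjusted p = 3e-08), and 8 of 16 duct genes fell with 1 up, 8 and 2 adjusted over the list alone (median -0.36, camera adjusted p = 0.037).

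The remaining low-dose list calls against the GFP vector, the duct list among them, depended on single libraries. Without GFP vector replicate 2, camera's adjusted p was 0.05 for the ATF4 list, 0.075 for hypoxia, 0.052 for NRF2, 0.05 for TGF-beta and 0.075 for duct genes. Without low-dose replicate 2 it was 0.055, 0.089, 0.061, 0.061 and 0.061 in the same order, and hypoxia was also lost without low-dose replicate 3 (adjusted p = 0.053). With all libraries, the ATF4 list had 8 of 20 genes down and 1 up, 9 and 2 adjusted over the list alone (median -0.28, camera adjusted p = 0.022). The hypoxia list had 11 of 22 down and 5 up (median -0.42, camera adjusted p = 0.047), the NRF2 list 8 of 19 down and 1 up (median -0.20, camera adjusted p = 0.026) and the TGF-beta list 7 of 23 down and 3 up (median -0.18, camera adjusted p = 0.03), all also adjusted over the list alone. With an estimated correlation adjusted p was 0.38 for each of these lists and for duct genes, and the hypoxia call was also lost with a block for replicate number (adjusted p = 0.054). In these lists PGK1, a glycolytic kinase, fell by 2.45 ± 0.09, from 8830 ± 806 to 1620 ± 114, but much of that difference lies in the GFP vector cells. Their PGK1 level was 1.72 ± 0.09 above parental cells, and the low-dose level was below parental cells by less (-0.73 ± 0.09). ENO1 fell by 1.31 ± 0.10 and SNAI2, an epithelial-mesenchymal transition factor gene, by 1.49 ± 0.10, while PFKFB4 rose by 1.14 ± 0.11. Mitochondrially encoded genes had a median of 0.09 (camera adjusted p = 0.6). Adhesion genes had a median of -0.03 and a mean of 0.04 with the test pointing up, and endothelial markers a median of -0.34 and a mean of 0.01 with the test pointing down (camera adjusted p = 0.64 and 0.78).

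The largest rises at the low dose included ABCG1 and ABCA1, cholesterol exporters, at 2920 ± 302 against 639 ± 50.9 (log2 fold change 2.19 ± 0.10, adjusted p = 3.5e-13) and 1550 ± 122 against 511 ± 91.3 (1.61 ± 0.13, adjusted p = 2.7e-09). Part of the ABCA1 difference lies in the GFP vector cells, whose ABCA1 level was below that of parental cells. IL1RL1, the receptor for interleukin 33, rose by 1.90 ± 0.10 to 5630 ± 349, and HID1 and SMTNL1 rose by 2.12 ± 0.19 and 1.99 ± 0.26. Over all genes, limma called 6336 (35.1%), 2809 higher and 3527 lower, with 688 and 481 changed at least 2-fold. The majority depends on the scaling, with 3449 higher and 2930 lower after upper-quartile scaling and 2664 and 3719 after TMM. On whole reads, edgeR called 6335 and DESeq2 6183.

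The direct comparison of the 2 HBP1 doses, made with the same vector, asks which changes depended on dose. FGFBP1, a carrier that releases fibroblast growth factors, stood at 35500 ± 4100 in high-dose cells against 1820 ± 391 in low-dose cells (log2 fold change 4.30 ± 0.13, adjusted p = 3.6e-18). S100A2, a calcium-binding protein of basal epithelium, stood at 21400 ± 649 against 1500 ± 334 (3.85 ± 0.12, adjusted p = 5.5e-18), and the peptide hormone gene APLN at 606 ± 112 against 27.1 ± 6.29. MX2 stood at 64.1 ± 9.11 against 9100 ± 336 (-7.14 ± 0.10, adjusted p = 6e-24), and all 32 interferon-stimulated genes fell, also adjusted over the list alone (median -3.84, camera adjusted p = 1.5e-45). MMP13 fell by 6.43 ± 0.21 and CH25H, an interferon-induced sterol hydroxylase gene, by 5.45 ± 0.35. All 31 G1/S genes and all 34 G2/M genes were higher at the high dose, also adjusted over the list alone (medians 1.38 and 0.92, camera adjusted p = 1e-20 and 8.6e-20). UHRF1 stood at 1820 ± 80.6 against 311 ± 16.9 (2.55 ± 0.09, adjusted p = 8.6e-17) and KIF20A at 921 ± 50.2 against 235 ± 10.2 (1.96 ± 0.09, adjusted p = 1.4e-14). MYC was higher at the high dose by 0.73 ± 0.08 and H1F0 lower (-1.61 ± 0.11), while CDKN1A was lower (-0.36 ± 0.09, adjusted p = 0.0017).

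Between the doses, hypoxia and glycolysis genes rose in 20 of 22 cases and fell in 1, also adjusted over the list alone (median 1.09, camera adjusted p = 2.4e-10), with LDHA at 8580 ± 260 against 2120 ± 258. Cholesterol genes rose in 20 of 22 cases, 21 adjusted over the list alone (median 1.20, camera adjusted p = 2.7e-13, adjusted p = 0.062 with an estimated correlation). Squamous genes rose in 21 of 34 cases and fell in 2, 21 and 3 adjusted over the list alone (median 1.16, camera adjusted p = 3.4e-06, adjusted p = 0.17 with an estimated correlation), with KRT14 at 64700 ± 3960 against 10400 ± 1550. NRF2 genes rose in 14 of 19 cases and fell in 1 (median 0.78, camera adjusted p = 6.6e-06), leukocyte markers rose in 4 of 5 (median 1.35, camera adjusted p = 0.013), and both had adjusted p = 0.17 with an estimated correlation. Ribosomal protein genes rose in 18 of 34 cases (median 0.32), with adjusted p = 0.61 with an estimated correlation, and mitochondrially encoded genes in 10 of 13 (median 1.13), with adjusted p = 0.46 with an estimated correlation; camera gave adjusted p = 0.00022 for both. AP-1 genes rose in 15 of 24 cases and fell in 2 (median 0.56, camera adjusted p = 0.00072), TGF-beta genes rose in 9 of 23 and fell in 2 (median 0.22, camera adjusted p = 0.011), and both had adjusted p = 0.42 with an estimated correlation. FOS and SNAI2 were higher at the high dose by 2.88 ± 0.15 and 2.42 ± 0.10. The 6 lists from NRF2 to TGF-beta had the same counts adjusted over the list alone.

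Some lists were lower at the high dose than at the low dose. ATF4 genes fell in 15 of 20 cases and rose in 1, also adjusted over the list alone (median -0.53, camera adjusted p = 1.3e-06, adjusted p = 0.12 with an estimated correlation), with ASNS down by 2.44 ± 0.12 on the log2 scale (from 1270 ± 26.6 to 238 ± 54.5). Unfolded protein response genes fell in 11 of 18 cases and rose in 4, also adjusted over the list alone (median -0.64, camera adjusted p = 0.0047, adjusted p = 0.46 with an estimated correlation), with ERN1, the sensor IRE1, at 900 ± 115 against 3820 ± 293. p53 targets fell in 13 of 24 cases, 14 adjusted over the list alone, and rose in 5 (median -0.35, camera adjusted p = 0.0076, adjusted p = 0.17 with an estimated correlation). NF-kB genes split, 7 of 22 up and 9 down, also adjusted over the list alone (median -0.02, camera adjusted p = 0.59), with CSF3 higher at the high dose by 1.49 ± 0.09 and IRF1 lower (-1.49 ± 0.10). Histone genes had a median of 0.22 and a mean of 0.11 with the test pointing down, and fibroblast markers a median of 0.23 and a mean of -0.34 with the test pointing up (camera adjusted p = 0.95 and 0.86). Over all genes, limma called 9080 (50.4%), 4601 higher and 4479 lower, with 1483 and 1296 changed at least 2-fold, edgeR called 9187 and DESeq2 8986. TMM scaling gave 4430 higher and 4676 lower, and upper-quartile scaling 4543 and 4612.

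Against the shared GFP vector control, 3675 genes were called at both doses. Of these, 1084 rose and 1393 fell at both, against 657.3 and 863.1 for independent lists of the same sizes. Another 1198 went opposite ways, 754 up at the high dose and down at the low dose (825.4 for independent lists) and 444 the reverse (687.4). Cell cycle genes such as UHRF1 lie in the former set, and MYC, CXCL8 and TNFSF18 fell at both doses. Across genes, which are not independent replicates, the fold changes at the 2 doses had a Pearson r of 0.305. Groups simulated without any change against the same controls gave 0.498 (0.466 to 0.528 over 100 draws) through the shared controls alone. The same sign was held by 59.2% of genes against 66.6% simulated. Noise in groups of equal size gives about these simulated values whatever the data. The observed fold changes hold more than noise, so neither r nor the share of equal signs can be judged against the draws. The covariance can be judged against noise alone, and it was 0.147 against 0.04 simulated (highest draw 0.042), a difference of 0.107. GFP vector cells differed from parental cells in 2435 genes. Where the HBP1 groups lack such a change, it enters both comparisons and adds covariance without any HBP1 effect. The draws hold no such change, so the difference does not measure a response shared by the doses. The control has 3 libraries, too few to give each dose at least 2 of its own, so part of the overlap may come from the shared controls.

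The comparison of GFP vector with parental cells asks what transduction with a control vector did at 575 infection units per cell. It is not a matched background for the HBP1 groups, which received 3.25 and 32.5 infection units per cell. RSAD2 stood at 25200 ± 2290 in GFP vector cells against 7350 ± 1840 in parental cells (log2 fold change 1.80 ± 0.13, adjusted p = 3.6e-09), and ISG15, a ubiquitin-like antiviral modifier, at 16700 ± 1950 against 5800 ± 1010 (1.53 ± 0.13, adjusted p = 1.9e-08). Of 32 interferon-stimulated genes, 30 rose, 31 adjusted over the list alone (median 0.77, camera adjusted p = 3.3e-36, adjusted p = 0.067 with an estimated correlation). Among the largest rises outside the list were LCN2 at 2920 ± 472 against 736 ± 73.7 (1.98 ± 0.10, adjusted p = 8e-12), the complement protease gene C1R (1.92 ± 0.12) and the chemokine gene CCL5 (2.06 ± 0.24). The acute phase genes SAA1 and SAA2 rose by 1.99 and 1.96, and are uncertain because they share reads. FGF19, a secreted growth factor gene, rose most, from 25.3 ± 12.1 to 265 ± 51.3 (3.44 ± 0.34, adjusted p = 2.1e-07). HMGCS1 fell from 2200 ± 439 to 746 ± 37.9 (-1.54 ± 0.11, adjusted p = 2.1e-09), the metallothionein genes MT1E and MT2A fell by 1.51 ± 0.11 and 1.33 ± 0.11, and HMGA2 by 1.21 ± 0.08. PGK1 rose from 2670 ± 115 to 8830 ± 806 (1.72 ± 0.09, adjusted p = 8e-12).

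Cell cycle genes were lower in GFP vector than in parental cells. Of 34 G2/M genes, 28 fell, 30 adjusted over the list alone (median -0.43, camera adjusted p = 7.2e-25), and of 31 G1/S genes 21 fell, 24 adjusted over the list alone (median -0.40, camera adjusted p = 9.7e-15). DLGAP5 fell by 0.73 ± 0.09, KIF20A by 0.72 ± 0.09 and E2F1 by 0.84 ± 0.10, while MYC (-0.13 ± 0.08, adjusted p = 0.31) did not differ detectably. Cholesterol synthesis genes fell in 14 of 22 cases, 16 adjusted over the list alone (median -0.46, camera adjusted p = 2.3e-13, adjusted p = 0.076 with an estimated correlation). Squamous genes rose in 14 of 34 cases and fell in 1, 17 and 2 adjusted over the list alone (median 0.38, camera adjusted p = 3e-07, adjusted p = 0.21 with an estimated correlation), with KRT6B up by 0.94 ± 0.10. Unfolded protein response genes rose in 7 of 18 cases, also adjusted over the list alone (median 0.19, camera adjusted p = 0.0016, adjusted p = 0.53 with an estimated correlation). Mitochondrially encoded genes fell in 4 of 13 cases, 5 adjusted over the list alone (median -0.54, camera adjusted p = 0.0036, adjusted p = 0.65 with an estimated correlation). MT-CO1 fell by 1.23 ± 0.30 (adjusted p = 0.0064), a call lost without GFP vector replicate 2 (adjusted p = 0.056).

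Further list calls between GFP vector and parental cells depended on single libraries. ATF4 genes rose in 4 of 20 cases (median 0.17, camera adjusted p = 0.013, adjusted p = 0.52 with an estimated correlation), and the call was lost without GFP vector replicate 2 (adjusted p = 0.054). Ribosomal protein genes rose in 4 of 34 cases (median 0.13, camera adjusted p = 0.013, adjusted p = 0.76 with an estimated correlation), lost without parental replicate 1 (adjusted p = 0.053), GFP vector replicate 2 (0.29) or GFP vector replicate 3 (0.091). p53 targets rose in 6 of 24 cases (median 0.09, camera adjusted p = 0.042, adjusted p = 0.45 with an estimated correlation), lost without parental replicate 1 (adjusted p = 0.12) or GFP vector replicate 2 (0.073). Their strongest member, GDF15, rose from 554 ± 22.8 to 1430 ± 179 (1.36 ± 0.10). Wnt targets fell in 3 of 13 cases and rose in 1, with a median of 0.00 and a mean of -0.17 (camera adjusted p = 0.033, adjusted p = 0.45 with an estimated correlation), lost without parental replicate 3 (adjusted p = 0.084), GFP vector replicate 1 (0.052) or GFP vector replicate 3 (0.058). These 4 lists had the same counts adjusted over the list alone, and FOSL1 and DKK1 fell by 0.91 ± 0.09 and 0.79 ± 0.10. The duct list (median 0.17, camera adjusted p = 0.074) passed without parental replicate 2 (adjusted p = 0.031). NF-kB genes split, 6 of 22 up and 4 down, 7 and 4 adjusted over the list alone (median 0.08, camera adjusted p = 0.51). Medians, means and tests differed in sign for histone genes (0.12, -0.03, up), reported HBP1 targets (0.02, 0.06, down) and TGF-beta genes (0.07, 0.03, down). Over all genes, limma called 2435 (13.5%), 1315 higher and 1120 lower, with 219 and 198 changed at least 2-fold, edgeR called 2420 and DESeq2 2499. After upper-quartile scaling 1213 were higher and 1250 lower. The limma count was 1621 without parental replicate 1, 1420 without parental replicate 3 and 1469 without GFP vector replicate 2.

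The comparison of high-dose HBP1 with parental cells sets the high dose against cells that never met a vector. MX2 stood at 64.1 ± 9.11 against 7050 ± 1080 (log2 fold change -6.76 ± 0.10, adjusted p = 2.1e-23), and all 32 interferon-stimulated genes fell, also adjusted over the list alone (median -3.13, camera adjusted p = 2.9e-56). The chemokine gene CXCL2 stood at 592 ± 62.9 against 4080 ± 299 (-2.78 ± 0.09, adjusted p = 2.7e-17), and 20 of 22 NF-kB genes fell, 20 with 1 up adjusted over the list alone (median -1.16, camera adjusted p = 2e-17). ATF4 genes fell in 16 of 20 cases (median -0.74, camera adjusted p = 8.1e-11) and hypoxia genes rose in 17 of 22 and fell in 1 (median 0.68, camera adjusted p = 9.1e-10), both also adjusted over the list alone. CA9, a carbonic anhydrase induced by hypoxia, stood at 228 ± 11.8 against 37.7 ± 2.17 (2.56 ± 0.21, adjusted p = 1.3e-09). Squamous genes rose in 22 of 34 cases and fell in 4, also adjusted over the list alone (median 1.06, camera adjusted p = 1.2e-09, adjusted p = 0.093 with an estimated correlation). The envelope genes CNFN and SBSN rose by 3.13 ± 0.29 and 3.11 ± 0.17, and KRT16 from 1010 ± 51.9 to 3970 ± 417 (1.98 ± 0.09, adjusted p = 5.1e-14). G1/S genes rose in 21 of 31 cases, 22 adjusted over the list alone (median 0.49, camera adjusted p = 4.7e-09, adjusted p = 0.077 with an estimated correlation), with FEN1 up by 1.12 ± 0.10.

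G2/M genes were level between high-dose and parental cells, with 3 of 34 up and 2 down, 3 up adjusted over the list alone (median 0.00, mean 0.03, camera adjusted p = 0.72). MYC fell by 1.30 ± 0.08 and H1F0 by 1.64 ± 0.11, while EZH2 rose by 0.35 ± 0.09 and DNMT1 (0.14 ± 0.08, adjusted p = 0.19) did not differ detectably. NRF2 genes rose in 14 of 19 cases and fell in 2 (median 0.59, camera adjusted p = 6.1e-05, adjusted p = 0.26 with an estimated correlation). Cholesterol genes rose in 12 of 22 cases and fell in 1 (median 0.27), with adjusted p = 0.36 with an estimated correlation, and mitochondrially encoded genes rose in 9 of 13 (median 0.71), with adjusted p = 0.58 with an estimated correlation. Camera gave adjusted p = 0.00037 for both of the latter, and these 3 lists had the same counts adjusted over the list alone. CSF1R rose from 47.9 ± 5.49 to 149 ± 19.7 and CD14 from 29.3 ± 10.7 to 93 ± 10. The leukocyte list passed by camera with TMM scaling (adjusted p = 0.043), without parental replicate 2 (0.034) or without high-dose replicate 2 (0.033). The adhesion list passed without high-dose replicate 3 (0.023). Beside G2/M, the median, mean and test differed in sign for p53 targets (0.08, -0.14, down), reported HBP1 targets (0.02, -0.11, down), unfolded protein response genes (0.22, -0.01, up), duct genes (-0.03, 0.05, up), ribosomal protein genes (0.00, 0.02, up) and fibroblast markers (-0.1, -0.18, up). Over all genes, limma called 7146 (39.6%), 3459 higher and 3687 lower, edgeR called 7262 and DESeq2 7094. Upper-quartile scaling turned the majority, with 3790 higher and 3393 lower.

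The comparison of low-dose HBP1 with parental cells sets the low dose against cells without virus. MYC stood at 1090 ± 19.1 against 4460 ± 330 (log2 fold change -2.03 ± 0.08, adjusted p = 1.9e-14), and all 34 G2/M genes fell, also adjusted over the list alone (median -0.89, camera adjusted p = 8.7e-28). RRM2 fell from 1040 ± 141 to 220 ± 16.3 (-2.22 ± 0.10, adjusted p = 1.5e-13), and 27 of 31 G1/S genes fell, also adjusted over the list alone (median -0.77, camera adjusted p = 3.1e-17). Of 22 NF-kB genes, 19 fell, also adjusted over the list alone (median -1.25, camera adjusted p = 4.3e-16), with IL1A down by 1.96 ± 0.09 on the log2 scale. Interferon-stimulated genes, in contrast, rose in 28 of 32 cases and fell in 1, also adjusted over the list alone (median 0.70, camera adjusted p = 3.3e-13, adjusted p = 0.25 with an estimated correlation), with RSAD2 up by 1.60 ± 0.13. Cholesterol genes fell in 19 of 22 cases, 20 adjusted over the list alone (median -0.88, camera adjusted p = 3.6e-13, adjusted p = 0.08 with an estimated correlation). Unfolded protein response genes rose in 13 of 18 cases, also adjusted over the list alone (median 0.58, camera adjusted p = 8.3e-07, adjusted p = 0.25 with an estimated correlation), with DNAJC3 at 4740 ± 458 against 2020 ± 34.9. CLGN, a chaperone of the endoplasmic reticulum, rose from 265 ± 14.4 to 1780 ± 111 (2.74 ± 0.11, adjusted p = 1.7e-14), and CAV1, a membrane scaffold, fell from 10900 ± 1860 to 1660 ± 219 (-2.71 ± 0.12, adjusted p = 8.5e-14). CDKN1A rose by 0.57 ± 0.09, and DNMT1 and EZH2 fell by 0.66 ± 0.08 and 0.50 ± 0.09.

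Smaller list shifts at the low dose against parental cells were past the threshold by camera and not with an estimated correlation. Ribosomal protein genes fell in 18 of 34 cases, 19 adjusted over the list alone (median -0.30, camera adjusted p = 1.8e-05, adjusted p = 0.56 with an estimated correlation). AP-1 genes fell in 12 of 24 cases and rose in 3, 12 and 4 adjusted over the list alone (median -0.27, camera adjusted p = 0.0049, adjusted p = 0.46 with an estimated correlation), with FOS down (-2.33 ± 0.15). p53 targets rose in 10 of 24 cases and fell in 2, also adjusted over the list alone (median 0.22, camera adjusted p = 0.016, adjusted p = 0.25 with an estimated correlation). Wnt targets fell in 5 of 13 cases and rose in 1, 7 and 1 adjusted over the list alone (median -0.21, camera adjusted p = 0.02, adjusted p = 0.25 with an estimated correlation). Hypoxia genes fell in 9 of 22 cases and rose in 4, 10 and 5 adjusted over the list alone (median -0.37, camera adjusted p = 0.024, adjusted p = 0.28 with an estimated correlation), with ENO1 down (-1.60 ± 0.10). NRF2 genes fell in 8 of 19 cases, also adjusted over the list alone (median -0.15, camera adjusted p = 0.026, adjusted p = 0.46 with an estimated correlation), lost without low-dose replicate 2 (adjusted p = 0.066). TGF-beta genes fell in 10 of 23 cases and rose in 3, 10 and 4 adjusted over the list alone (median -0.18, camera adjusted p = 0.041, adjusted p = 0.46 with an estimated correlation). That call was lost without parental replicate 2 (adjusted p = 0.052), parental replicate 3 (0.05) or low-dose replicate 2 (0.072). Adhesion genes had a median of 0.00 and a mean of 0.09, and islet markers a median of 0.20 and a mean of -0.01, each with the test pointing up. KRT19 fell by 1.28 ± 0.09 and OCLN, a tight junction gene, rose by 1.36 ± 0.12. Over all genes, limma called 6981 (38.7%), 3326 higher and 3655 lower, edgeR called 7057 and DESeq2 6906. The majority turned after upper-quartile scaling, with 3767 higher and 3317 lower.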

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

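The tests of scaling, single libraries, vector amount, read sharing and control position below were chosen only after the results had been seen, while the counts over other splits of the libraries had been planned. Each gene list given here drew attention because the change at the high HBP1 dose and the change at the low dose, both against GFP vector cells, differed in camera's test of the difference itself. The first value for each list is the median log2 difference between the doses.

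Interferon-stimulated genes differed most, by -3.84, with medians of -4.07 at the high dose and -0.07 at the low dose. Scaling of the libraries is argued against, since the high-dose median against parental cells was -3.16 with TMM and -3.1 with upper-quartile scaling. The edgeR and DESeq2 fits gave -3.14 each, but edgeR reuses TMM and the submitters also used DESeq2, so they add no further scaling. A single odd library is argued against too, because the high-dose library closest to the parental mean lay at -3.15. Less virus than in GFP vector cells would leave these genes at or above the parental level, yet their median against parental cells was -3.13. The difference in HBP1 dose remains open as the biological explanation, and so do culture day, density and batch, which are not given and go with the group.

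Mitochondrially encoded genes differed by 1.13, with medians of 1.29 at the high dose and 0.09 at the low dose, and adjusted p = 0.46 with an estimated correlation. High-dose replicate 3 had the highest mitochondrial share, but the median against GFP vector cells was 0.99 without it. One common factor for all mitochondrial RNA is argued against as the only cause, since MT-CO1 rose by 0.95 more than the median of the other 12 members against GFP vector cells; its log2 excess over them was 2.48 to 2.53 in high-dose, 2.11 to 2.14 in parental and 1.55 to 1.56 in GFP vector libraries, without overlap. The mitochondrial ribosomal RNA MT-RNR2, which is outside that list, showed no shared rise. It took 0.84%, 1.1% and 1.69% of reads in high-dose libraries against 1.14% to 1.41% in GFP vector libraries. Reads moving between MT-CO1 and its nuclear copies would cancel in their sum, which rose by 2.4. That sum is nearly all MT-CO1 and had to follow its change, so it adds no separate evidence. The largest copy, MTCO1P12, averaged 769 against 561300 for MT-CO1 at the high dose, too few reads to account for the rise. A common factor beside another cause, cell state, RNA quality and HBP1 itself stay open, since no measure of RNA quality was analysed here.

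G1/S and DNA replication genes differed by 1.38 and G2/M and mitosis genes by 0.92, with opposite signs at the doses (0.88 and -0.40, 0.45 and -0.55). Scaling is argued against for the G1/S difference between the doses, which was 1.36 with TMM and 1.37 with upper-quartile scaling. The edgeR and DESeq2 fits, which add no further scaling, gave 1.38 each. Medians under these scalings were not worked out for the G2/M list, or for either list against GFP vector cells. If only the position of the GFP vector control were the cause, the doses would not move opposite ways against parental cells. At the high dose G1/S genes averaged 0.5 above parental cells, against that reading (adjusted p = 4.7e-09, or 0.077 with an estimated correlation), while G2/M genes averaged 0.03, which is consistent with it. The rise of G2/M genes at the high dose may therefore reflect a lower GFP vector control, and culture density stays open for both lists.

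The other lists are given as values. Cholesterol synthesis genes differed by 1.2 between the doses, with medians of 0.59 at the high and -0.32 at the low dose. Basal keratin and squamous genes differed by 1.16 (0.53 and -0.28), and hypoxia and glycolysis genes by 1.09 (0.77 and -0.42). NRF2 genes differed by 0.78 (0.46 and -0.20), AP-1 genes by 0.56 (0.22 and -0.19) and TGF-beta genes by 0.22 (0.09 and -0.18). Leukocyte markers, 5 tested, differed by 1.35 (0.94 and -0.88), and ribosomal protein genes by 0.32 (-0.14 and -0.45). Unfolded protein response genes differed by -0.64 (-0.08 and 0.41), ATF4 genes by -0.53 (-0.89 and -0.28) and p53 targets by -0.35 (-0.19 and 0.09). Of these 11 lists, only hypoxia and glycolysis was past the threshold with an estimated correlation (adjusted p = 0.014), and the interferon, G1/S and G2/M lists were past it as well.

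Each pairwise comparison has 6 libraries, which make 10 splits, too few for a share under 0.05. In each comparison 1 of 10 splits, the real one, gave as many called genes. The highest other split gave 0 genes for each comparison except GFP vector against parental cells, where it gave 1, in fits that kept the other 6 libraries in their own groups. For the F test over 4 groups, 1 of 100 regroupings, the real one, gave as many genes as the 12133 called, and the highest other gave 4534. Random labels are thus an unlikely source of that count. Groups that differ for any reason, batch included, would give the same outcome, so it does not tell causes apart.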

How the results depend on the processing

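The setting without 2 libraries was added only after the results had been seen, and all other settings had been fixed before the values were opened. With a threshold of 0.01 in place of 0.05, 1433 genes changed the same way at both HBP1 doses against GFP vector cells and 663 opposite ways, in place of 2477 and 1198, because fewer genes pass a stricter threshold. Leaving out 1 library at a time gave 1420 to 2323 genes for GFP vector against parental cells in place of 2435. The count was 1621 without parental replicate 1, 1420 without parental replicate 3 and 1469 without GFP vector replicate 2, and each of these fits has fewer libraries; why these libraries weigh more than others was not tested. Adding the replicate number as a block gave 8735, 6506, 9184, 2648, 7279 and 7093 genes for the 6 comparisons in the order of the report. The labels do not say that equal numbers belong together, and of 18 correlations between libraries with the same number 1 was above 0.1 (range -0.204 to 0.106). The block changed the call of 1 list, hypoxia and glycolysis at the low dose against GFP vector cells (adjusted p = 0.054). No called change reversed its sign under any setting. An estimated correlation between genes removed 50 list calls, the largest effect of any setting on the lists, while fry removed 3 and added 32. Without the 2 libraries that stood apart, 4 list calls were lost and 3 gained. With 3 libraries per group, and with culture day, density and batch not given in the sources used here, no setting separates HBP1 from what else differed between the groups.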

Other observations

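The tests given here were chosen only after the results had been seen, and so were the gene lists and genes. In high-dose HBP1 cells antigen presentation genes fell together with the interferon-stimulated genes: 16 of 16 fell against GFP vector cells (median log2 change -1.37, camera adjusted p = 7.4e-14), and 10 fell against parental cells (median -0.55, adjusted p = 8.7e-07, or 0.079 with an estimated correlation). All 16 had risen in GFP vector cells (median 0.74, adjusted p = 1.8e-20). HLA genes share reads, so their single values are uncertain. TAP1 read 4417 ± 582 in parental, 9094 ± 981 in GFP vector, 7937 ± 1170 in low-dose and 1349 ± 267 in high-dose cells. Complement and acute phase genes rose in GFP vector cells, 10 of 10 (median 1.73, adjusted p = 2.1e-21), and 9 fell at the high dose against GFP vector cells (median -2.95, adjusted p = 3.7e-12). Against parental cells 8 fell, by less (median -1.01, adjusted p = 3.2e-06, or 0.079 with an estimated correlation). At the low dose 6 of these fell against GFP vector cells (median -0.75, adjusted p = 0.00096, or 0.51 with an estimated correlation), C3 among them (-1.73 ± 0.14, adjusted p = 3e-09).

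Other genes rose at the high dose. Of 16 heat shock chaperone genes 11 rose against GFP vector cells and 2 fell (median 0.71, adjusted p = 5.5e-05, or 0.052 with an estimated correlation), and against low-dose cells 11 rose and 1 fell (median 0.97). Against parental cells 10 rose and 3 fell (median 0.59, adjusted p = 1.3e-05, or 0.079 with an estimated correlation). HSPA8 rose from 3060 ± 114 to 14430 ± 672 (2.24 ± 0.09, adjusted p = 1.8e-15). All 4 metallothionein genes tested rose against GFP vector cells (median 1.86, adjusted p = 7.1e-05), where 3 had fallen against parental cells (median -1.22). High-dose cells lay closer to parental cells, with 2 of 4 up (median 0.84, adjusted p = 0.014, or 0.12 with an estimated correlation), and reads shared among these genes make single values uncertain. Of 11 liver X receptor targets 7 rose and 2 fell against GFP vector cells (median 0.74, adjusted p = 0.0024, or 0.093 with an estimated correlation), and 7 rose and 1 fell against parental cells (median 0.62, adjusted p = 0.0054, or 0.12 with an estimated correlation). The difference between the doses was not past the threshold for that list (adjusted p = 0.2). ABCA1 read 1098 ± 56.7 in parental cells, 511.2 ± 91.3 in GFP vector cells and 2460 ± 541 in high-dose cells. Its low-dose mean lay between those of parental and high-dose cells.

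The low interferon-stimulated genes of high-dose cells may follow from less interferon RNA. The summed reads of IFNB1, IFNL1 and IFNL2 were 124 in parental, 318 in GFP vector, 134 in low-dose and 9 in high-dose cells, and no high-dose library exceeded 0.28 RPM, below all 9 other libraries. Interferon RNA and these genes were both higher in GFP vector than in parental cells, but at the low dose they did not go together. Low-dose libraries, at 2.03 to 3.57 RPM, overlapped parental ones (1.27 to 3.31 RPM) and lay below GFP vector ones (5.97 to 7.93 RPM). Yet interferon-stimulated genes at the low dose were near GFP vector cells (median log2 change -0.07) and above parental cells. Interferon RNA alone therefore does not account for their level in every group. Less receptor RNA is argued against, since the lowest change of IFNAR1, IFNAR2 and IFNLR1 against parental cells was 0.39. These counts are small, interferon protein was not analysed here, and the order of events is open. Interferon protein in the medium, or added interferon, would test this reading.

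PGK1 was 1.72 higher in GFP vector than in parental cells. A glycolysis or hypoxia response is argued against, since the other 21 genes of that list had a median of -0.11, with 1 risen and 3 fallen. A candidate explanation is vector sequence counted as PGK1, because lentiviral vectors often carry a PGK promoter, but the vector sequence is not given in the sources used here. That reading and a change of the gene itself cannot be told apart from 1 value per gene, and in low-dose cells PGK1 was -0.73 against parental cells. Reads along the gene would tell.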
